A study of Triticum aestivum with 36 samples.

How the data were processed

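The series measured transcript levels by RNA sequencing in root tips of wheat (Triticum aestivum) seedlings, with root apices dissected into 3 zones under a microscope. Per the labels' protocols, seedlings at the 3-leaf stage either received a mild osmotic priming treatment (5% polyethylene glycol, -0.37 MPa, for 6 h) or stayed in culture solution, and recovered for 6 days. Primed and unprimed plants were then either stressed with 15% polyethylene glycol (-0.78 MPa) for 24 h or left unstressed. Polyethylene glycol in the solution lowers its water potential and so imposes drought on roots. The sample titles give a code (CK, PD, CD or PC), a zone letter (A, B or C) and a number from 1 to 3, which makes 12 groups of 3 libraries. The labels spell out neither the codes nor where along the axis each zone lies. The codes are read here as CK without priming or stress, PC with priming alone, CD with stress alone and PD with both, and the groups are called by their codes throughout. No label says that the 3 libraries of a group came from separate cultures, so p-values measure only the spread between these samples.

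The deposited table holds expected counts and FPKM for 115115 IDs in 36 libraries. Bowtie2 2.2.8, TopHat2 2.1.1, RSEM 1.2.19 and Bowtie are named in the submitters' processing notes, with no role or order. The genome build and the annotation were not given in the sources used here, apart from the IDs, most of which carry TGACv1, the name of a wheat genome assembly. The expected counts made by the authors were whole in 72% of values, and they were rounded to whole numbers here before any test. The FPKM values made by the authors, which scale counts by library size and gene length, served only to derive the relative lengths of genes. For 32403 genes, that scaling returned the deposited FPKM within 5% for 98.6% of values. Of the IDs, 103459 start with TRIAE and 11656 with XLOC, and 20133 had no count in any library. Reference gene records used for names covered 155467 genes, and 0 IDs matched them. Genes are therefore given by ID alone, none of the 26 gene lists planned before the data were examined had members, and no list was tested. Wheat carries 3 subgenomes with near-identical gene copies whose reads the counting shares out, so a value for a single copy is uncertain.

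Library totals ranged from 14.2 M to 29 M expected counts (median 20.6 M). Libraries of a group differed beyond sampling noise in each of the 36 replicate pairs (mean chi-square per gene from 6.57 to 182), so none was counted as a duplicate. Groups with no count were set against a floor of 3 counts in each library, taken as CPM of its TMM-scaled total and averaged over the libraries of the group. Where a ratio of low counts is printed it carries an exact 95% interval. Some genes with few counts in the lower group are given only as a log2 fold change with its SE. Intervals and floors cover counting error only.

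Genes were tested with the quasi-likelihood F-test of edgeR 4.0.16 (R 4.3.3), with TMM factors, the filterByExpr filter (minimum count 10, minimum total 15) and 1 mean per group, over all 36 libraries. This left 69284 tested genes (59065 TRIAE and 10219 XLOC), which held 99.89% of the counts. A gene was called at a Benjamini-Hochberg adjusted p below 0.05. The comparisons were CD minus CK, PD minus PC, PD minus CD and PC minus CK in each zone, the zones of CK with each other, and F-tests of whether CD minus CK or PD minus CD differed between zones and whether PD minus PC differed from CD minus CK. Standard errors of log2 fold changes were derived from the F statistic. The rule for named genes was fixed before the data were examined. For IDs without a description it took, per comparison and direction, at most 2 called genes with the largest fold change, groups that did not overlap and a mean of at least 5 CPM (counts scaled to library size) in the higher group. The rule left PD minus PC out of naming, except for values of genes named elsewhere, and genes singled out beyond it are said to have been chosen after their values were seen. Log2 CPM used a prior count of 2.

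The test was tested on simulated data made from the real means and totals. For CD minus CK in zone C, with 66595 genes in the fit and 50 genes changed at each fold, it called 0% of genes changed 2-fold, 64% at 4-fold, 98% at 8-fold and 100% at 16-fold. It made 137 calls there, of which 6 were false, and 0 calls in zone A, where no gene was changed. Simulated counts were drawn independently, with a spread set by mean expression alone and equal in all groups. They held no spread particular to a gene or group, no pairing of zones by number and no outlying libraries. The simulation therefore does not show the rate of false calls in the real data.

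Numbers in the titles pair zones within a code. The deviations of same-numbered libraries from their group means correlated across genes at 0.12 to 0.81 (median 0.45) in all 36 pairs of zones of a code, and in 36 of 36 libraries the best match in both other zones had the same number. Counts of zone comparisons are therefore also given with code and number as a block. Alternatives planned before the data were examined were DESeq2 1.42.0, limma-voom (limma 3.58.1), median-ratio factors, no filter, a filter of 5 CPM in at least 3 libraries, fits to fewer libraries, blocks, a log2 fold change of at least 1 and leaving out each library. Those added after seeing the data were the fit to the 6 libraries compared, quality weights per group and code and number as a random block. Counts summed over zones, the block for zone differences of treatments and the fit without the 6 libraries of CK number 3 and PC number 1 were added then too.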

Results

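Expression was measured in 36 root apex libraries of wheat, from 12 groups of 3 libraries: the codes CK, PC, CD and PD in each of the zones A, B and C. Totals ranged from 14.2 M to 29 M expected counts, and 69284 genes were tested. The codes are read as unprimed and unstressed (CK), primed (PC), stressed (CD) and primed then stressed (PD). The design addresses how zones of the root apex respond to drought and whether an earlier mild drought changes that response. Genes are given by ID because the table does not pair IDs with names, and the chromosome arm is the one written in the ID.

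Zone set the first principal component (46.6% of variance), which ran from zone A through B to C in every code. The second (22.4%) parted CD and PD from CK and PC. Mean scores on it were -87.5 ± 9 (SD, n = 3) for CD and 83.8 ± 84.5 for CK in zone A. Libraries of a group did not lie equally close. The median SD of log2 CPM between libraries was 0.17, 0.19 and 0.24 in CD (zones A, B, C), 0.19, 0.23 and 0.24 in PD, 0.27, 0.31 and 0.31 in CK, and 0.38, 0.4 and 0.46 in PC. Each library was also placed on a scale from its CK or PC group mean (0) to the CD or PD group mean (1), with genes and weights from the other pair of codes. CK number 3 lay at 0.34 to 0.49 over the zones and PC number 1 at 0.27 to 0.43. The other CK and PC libraries lay at or below -0.02 and the lowest CD or PD library at 0.77. The mean set to 0 includes the library placed, so a high library pushes the others of its group below 0. CK number 1 lay at -0.39 to -0.32 and CK number 2 at -0.1 to -0.02, so CK was spread on both sides of its mean.

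**Figure D1:**
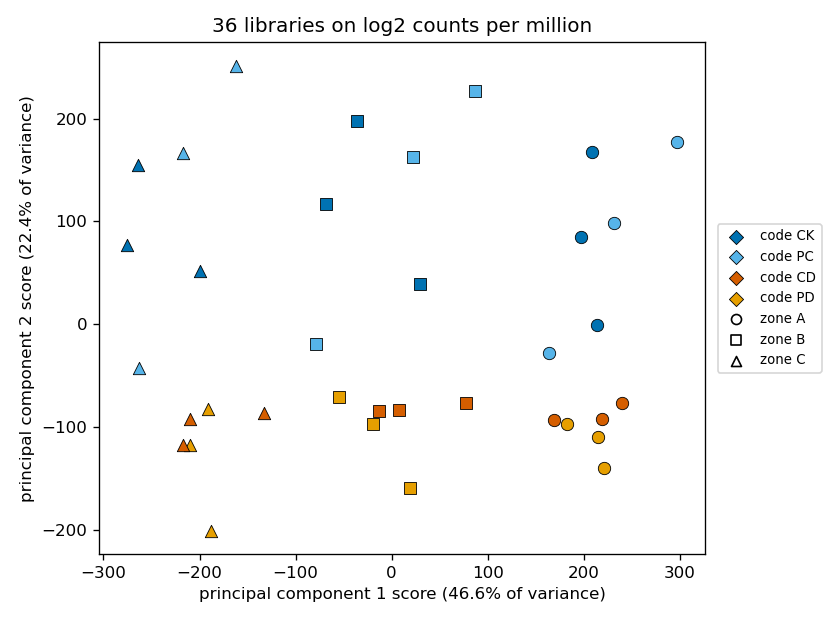
Scores of the 36 libraries on the first and second principal components of log2 CPM, with colour for code and symbol for zone. Zones part along the first component (46.6% of variance) and CD and PD from CK and PC along the second (22.4%). On the second, CD and PD libraries lie at or below -70.5 and CK and PC libraries at or above -42.8.

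**Figure D2:**
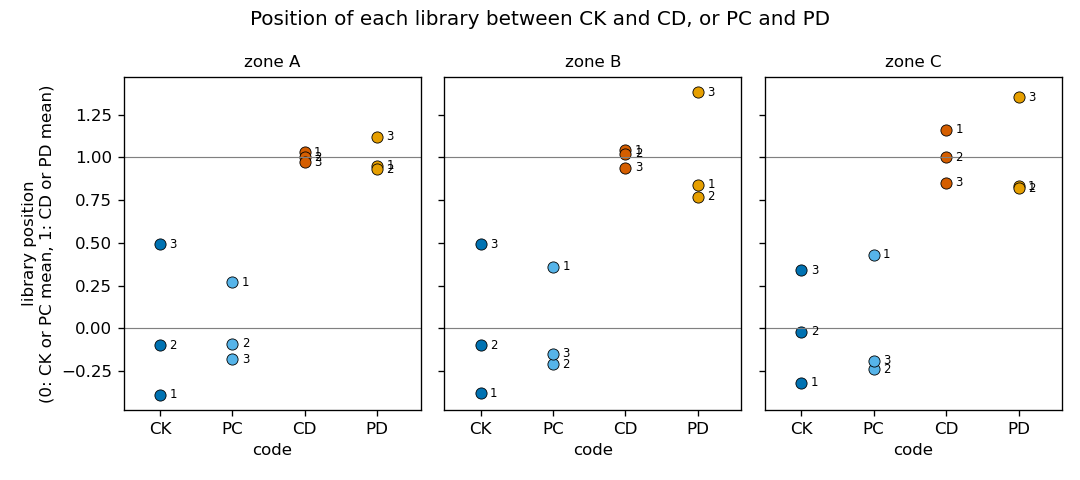
Position of each library between its CK or PC group mean (0) and the CD or PD group mean (1), per zone; each point is a library, with its number beside it. CK number 3 (0.34 to 0.49) and PC number 1 (0.27 to 0.43) lie above the other libraries of their groups in each zone.

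The zones of CK, the unprimed and unstressed code, differed in a large part of the genes. Between zones A and C, 34567 genes were called, 17068 higher in C and 17499 lower. From A to B there were 16349 calls (6731 higher in B, 9618 lower), and from B to C 11121 (5663 higher in C, 5458 lower). Higher and lower calls were close to equal from A to C and from B to C, and which were more numerous changed with the setting. From A to C it was 18455 higher and 16232 lower with median-ratio factors and 19085 and 16718 with DESeq2. Among other settings it was 22804 and 21990 with the block of code and number and 22234 and 22072 with it as a random block. Group quality weights gave 17455 and 17358, and leaving out CK number 3 and PC number 1 gave 18240 and 17939. From B to C it was 3927 and 5684 without a filter, 3959 and 5112 with the stricter filter, 4266 and 4960 with the CK libraries alone, 3351 and 3573 with the 6 libraries compared, and 5297 and 6111 without CK number 3 and PC number 1. TRIAE_CS42_1DS_TGACv1_080261_AA0244650 had 155 to 437 counts in zone C and 0 in the 3 zone A libraries, at least 127-fold higher, and TRIAE_CS42_2DS_TGACv1_177279_AA0572220 was at least 134-fold higher. In the other direction, TRIAE_CS42_4BL_TGACv1_320762_AA1048120 (139 to 239 counts in zone A, 0 in zone C) was at least 57.9-fold lower. TRIAE_CS42_2DL_TGACv1_157893_AA0500610 fell from 6.5 ± 2.58 to 0.0347 ± 0.031 CPM (SD, n = 3), a count ratio of 200 (95% interval 55.2 to 1660). From A to B, TRIAE_CS42_1AL_TGACv1_000216_AA0006420 rose by a log2 fold change of 6.49 ± 1.22 (SE; edgeR adjusted p = 0.00042) and TRIAE_CS42_4BL_TGACv1_321657_AA1063720 by 6.16 ± 1.37 (0.0019 in the same test). TRIAE_CS42_2BL_TGACv1_130517_AA0412740 changed by -5.38 ± 0.75 and TRIAE_CS42_6DL_TGACv1_527206_AA1700490 by -5.25 ± 0.72. From B to C, TRIAE_CS42_5DS_TGACv1_456767_AA1477720 (102 to 192 counts in zone C, 0 in zone B) was at least 51.2-fold higher, and TRIAE_CS42_3B_TGACv1_225330_AA0807140 rose by 6.76 ± 1.53. TRIAE_CS42_2AL_TGACv1_096086_AA0317060 changed by -3.63 ± 0.75 and TRIAE_CS42_1BL_TGACv1_031259_AA0110540 by -3.52 ± 0.97. With code and number as a block the counts were 30883 (A to B), 44794 (A to C) and 27281 (B to C). Without CK zone B number 2, A to B gave 9051 calls; without zone B number 3, zone C number 1 or zone C number 2, B to C gave 6094, 7025 and 5571. The 5DS call ended without zone B number 1, 2 or 3 or zone C number 2 (adjusted p = 0.056, 0.054, 0.064 and 0.055), and the 1BL call without zone B number 1 or zone C number 2 or 3 (0.061, 0.052 and 0.051). The 4BL call from A to C (TRIAE_CS42_4BL_TGACv1_320762_AA1048120) ended with code and number as a random block (0.11), limma-voom (0.11) and group quality weights (0.15), the 5DS call with DESeq2 (0.37), and the 1BL call with limma-voom (0.073) and group quality weights (0.088).

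CD minus CK, the response to stress in unprimed plants, held 1989 called genes in zone A (656 higher, 1333 lower), 4973 in zone B (2140 and 2833) and 6720 in zone C (2451 and 4269). The balance of higher and lower calls turned in zones A and B with limma-voom (837 higher and 795 lower, 2586 and 1898) and with code and number as a random block (1873 and 1325, 3953 and 2625), and in zone B with group quality weights (5828 and 5593). Of the 9370 genes called in at least 1 zone, 194 were higher and 589 lower in all 3, and 2 had opposite signs. TRIAE_CS42_2BL_TGACv1_130133_AA0404650 rose from 0.905 ± 0.633 to 60.4 ± 66.8 CPM (SD, n = 3) in zone A and from 0.0994 ± 0.0881 to 23.3 ± 28.7 in zone B, by log2 fold changes of 6.06 ± 1.25 and 7.78 ± 1.49 (SE; edgeR adjusted p = 0.012 and 0.0052). TRIAE_CS42_3B_TGACv1_226686_AA0818730 rose to 7.92 ± 4.89 CPM in zone B and 15.3 ± 6.02 in zone C, from 0.0564 ± 0.0638 and 0.117 ± 0.0709. TRIAE_CS42_U_TGACv1_641065_AA2083870 rose by 6.21 ± 1.49 in zone A and TRIAE_CS42_7BL_TGACv1_576795_AA1855220 by 6.14 ± 1.53 in zone C. TRIAE_CS42_3B_TGACv1_227850_AA0824910 fell from 138 to 175 counts to 0 in zone A, at least 43.1-fold lower. TRIAE_CS42_5AL_TGACv1_374280_AA1195940 was at 0 in the CD libraries of zones B and C, at least 81-fold and 101-fold lower than CK, and TRIAE_CS42_5DS_TGACv1_456767_AA1477720 at least 38.9-fold lower in zone C. TRIAE_CS42_3AL_TGACv1_203951_AA0670820 changed by -6.77 ± 1.3 in zone A and TRIAE_CS42_6DL_TGACv1_527012_AA1697190 by -7.73 ± 1.16 in zone B.

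Genes high in zone C took a large share of the lower calls. Among 14562 genes called at least 2-fold higher in zone C than A in PC, which shares no library with CD minus CK, 75 were higher and 2600 lower in zone C, 90 and 1903 in zone B, and 128 and 523 in zone A. Among 15723 genes high in zone A of PC, 976 were higher and 175 lower in zone C, 784 and 107 in zone B, and 73 and 218 in zone A. The genes of neither group were 1400 higher and 1494 lower in zone C. Set against the other genes, the zone C group stood 1.27 ± 0.3 log2 units (SD, n = 3) above them in CK zone C and 0.54 ± 0.22 in CD (two-sided exact permutation p = 0.1, the smallest possible with 3 against 3). The same test gave 0.2 for that group in zones A and B and 0.6, 1 and 0.2 for the genes high in zone A (zones C, B, A). Zone C to A differences were also taken as slopes on those of CK, over the 34567 genes called between these zones in CK. Slopes were 0.62 ± 0.05 in CD, 0.63 ± 0.04 in PD and 0.72 ± 0.02 in PC (SD). The exact permutation p was 0.1 for CD or PD against PC and 0.8 for PD against CD (n = 3). Choosing genes by CK and the prior count in log2 CPM both lower each slope. A slope below 1 therefore does not measure a gradient flatter than in CK.

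The counts of CD minus CK moved with single libraries. In zone A they were 203, 618 and 4615 without CK number 1, 2 or 3 and 595, 266 and 359 without CD number 1, 2 or 3. In zone B they were 470, 1318 and 8570 without the CK libraries in that order, and 2097, 402 and 1110 without those of CD. In zone C they were 1683 and 2791 without CK number 1 or 2, and 3760, 1535 and 2738 without CD number 1, 2 or 3. Leaving out the 6 libraries of CK number 3 and PC number 1, a choice that rests on the outcome, gave 14562, 18549 and 17739 calls (zones A, B, C). A fit to the 12 libraries of each zone gave 1503, 1510 and 2134. Of the 12 gene and zone pairs named for this comparison, 9 lost their call without at least 1 single library and 3 did not.

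The libraries that ended those 9 calls were as follows, with the edgeR adjusted p reached without each. In zone A the call of TRIAE_CS42_U_TGACv1_641065_AA2083870 ended without CK number 1 or 2 (0.14 and 0.078) or CD number 1 or 3 (0.1 and 0.055). That of TRIAE_CS42_2BL_TGACv1_130133_AA0404650 ended without CK number 1 or 2 (0.085 and 0.054) or CD number 1 (0.058), and that of TRIAE_CS42_3AL_TGACv1_203951_AA0670820 without CD number 2 (0.052). In zone B TRIAE_CS42_3B_TGACv1_226686_AA0818730 and TRIAE_CS42_5AL_TGACv1_374280_AA1195940 lost theirs without CK number 1 (0.15 and 0.13), CK number 2 (0.11 and 0.074), CD number 1 (0.068 and 0.097), CD number 2 (0.071 and 0.13) or CD number 3 (0.072 and 0.1). In zone C the 3B and 7BL genes lost theirs without CK number 1 (0.082 and 0.071) or CK number 2 (0.063 and 0.05). The 5AL and 5DS genes did so without CK number 1 (0.08 and 0.094), CD number 1 (0.076 and 0.084), CD number 2 (0.1 and 0.11) or CD number 3 (0.08 and 0.089), and the 5DS gene also without CK number 2 (0.081). Other settings ended calls too. Limma-voom did so for the U and 3AL genes in zone A (0.096 and 0.15), the 2BL, 3B and 5AL genes in zone B (0.067, 0.051 and 0.25) and the 5AL gene in zone C (0.24). Group quality weights did so for the U gene (0.072), the 2BL gene in zone B (0.1) and the 5AL gene in zone C (0.076), and the random block for the 3AL gene (0.15) and the 5AL gene in zones B and C (0.26 and 0.25). The 12 libraries of the zone did so for the 3B and 5AL genes in zone B (0.053 and 0.065) and the 5AL and 5DS genes in zone C (0.082 for both), and DESeq2 for the 5DS gene (0.39).

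PD minus PC, the response to stress in primed plants, held 8071 called genes in zone A (3440 higher, 4631 lower), 11997 in zone B (5465 and 6532) and 21540 in zone C (8555 and 12985). The balance turned in zones A and B with limma-voom (4440 higher and 3788 lower, 7264 and 5346) and with code and number as a random block (5904 and 4113, 8553 and 5864), in zone B with group quality weights (5244 and 4878), and in zone C without CK number 3 and PC number 1 (17075 and 16429). The counts of PD minus PC exceeded those of CD minus CK, but a count is not a size of response. The median absolute log2 fold change was 0.56, 0.62 and 0.73 (zones A, B, C), against 0.47, 0.53 and 0.54 in CD minus CK. Such a median also grows with the spread between libraries, which was widest in PC (median SD 0.38, 0.4 and 0.46). In PC minus CK, with at most 1 call per zone, it was 0.23, 0.25 and 0.33. The larger medians therefore do not show a stronger response in primed plants. Among genes called in CD minus CK, a choice that favours its values, the median ratio of PD minus PC to it was 0.71, 0.65 and 0.75. A later test of the difference per zone called 0, 0 and 407 genes. PD minus PC went the same way as CD minus CK, with which it shares no library. Of the genes called in CD minus CK, 96.1%, 93.9% and 92.9% had the same sign (zones A, B, C), and 989, 2108 and 3893 were called with that sign. Across genes, which are not independent replicates, the log2 fold changes of both correlated at 0.57, 0.56 and 0.56. Higher calls of both shared 361, 1035 and 1317 genes, against 32.6, 169 and 303 for independent lists, and lower calls shared 628, 1073 and 2576, against 89.1, 267 and 800. Genes high in zone C of CK (14389) were more often lower than higher in zone C, 3409 (23.7%) against 804 (5.59%), as were the genes of neither zone group, 7813 (19.3%) against 5080 (12.6%). The genes high in zone C stood 0.77 ± 0.09 log2 units above the other genes in PC zone C and 0.45 ± 0.12 in PD (SD, n = 3; exact permutation p = 0.1). The genes high in zone A of CK (14464) were 2671 higher and 1763 lower there, but 628 higher and 1876 lower in zone B and 263 higher and 1546 lower in zone A. For the genes high in zone C the counts were 875 and 1012 (7.03% lower) in zone B and 660 and 708 (4.92% lower) in zone A, below the 9.01% and 5.88% lower among genes of neither group. By library, the exact permutation p was 0.8, 0.4 and 0.3 for the genes high in zone A (zones C, B, A) and 0.7 and 0.6 for those high in zone C (zones B, A).

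**Figure D3:**
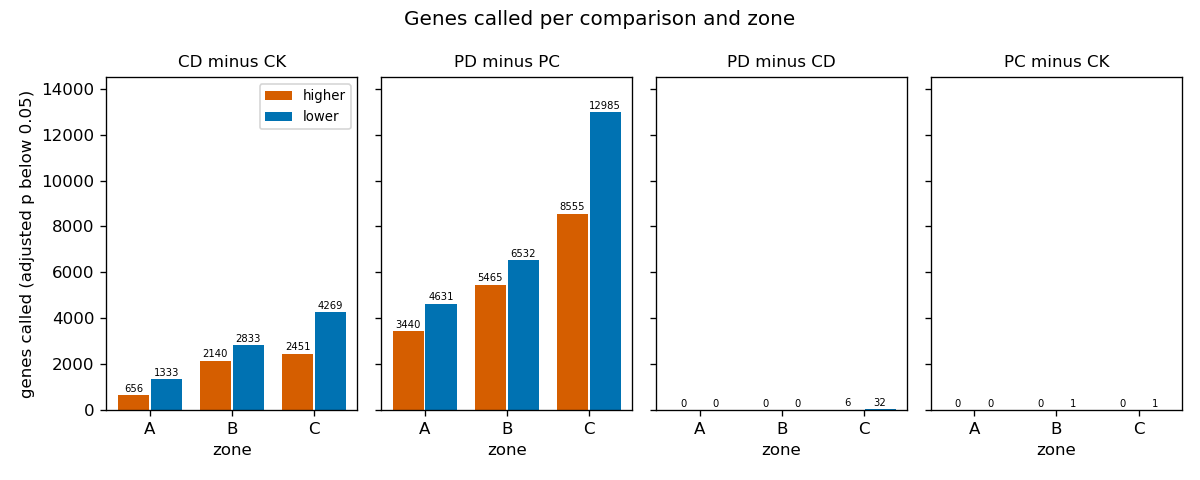
Genes called higher (orange) and lower (blue) at an adjusted p below 0.05 in 4 comparisons and 3 zones, with the counts above the bars. CD minus CK and PD minus PC hold 1989 to 21540 genes, PD minus CD at most 38 and PC minus CK at most 1.

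A fit of PD minus PC to the 6 libraries compared gave 2127, 0 and 0 calls in zones A, B and C, with 16247, 16014 and 19055 genes at an unadjusted p below 0.05 by edgeR. With all 36 libraries limma-voom gave 8228, 12610 and 21603, DESeq2 11736, 15440 and 23246, and group quality weights 9061, 10122 and 13207. Without PD number 1, 2 or 3 zone A gave 3032, 4808 and 1526 calls, and without PC number 1, 2 or 3 it gave 13277, 4490 and 1621. Zone B gave 5179 and 2461 without PD number 1 or 3, and 19785, 5577 and 2627 without PC number 1, 2 or 3. Zone C gave 12461 without PD number 3 and 10730 without PC number 3. Leaving out CK number 3 and PC number 1 in all zones gave 21649, 27009 and 33504.

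PD minus CD, which asks whether priming changed expression under stress, held 38 called genes in zone C, 6 higher and 32 lower in PD. TRIAE_CS42_6AL_TGACv1_471582_AA1511400 rose from 73.1 ± 26.3 to 329 ± 96.3 CPM (SD, n = 3), a log2 fold change of 2.17 ± 0.37 (SE; edgeR adjusted p = 0.035). TRIAE_CS42_5AL_TGACv1_374155_AA1191910 rose from 4.65 ± 0.605 to 14.3 ± 5.54 CPM, by 1.62 ± 0.3. TRIAE_CS42_7DS_TGACv1_622209_AA2035330 fell from 29.6 ± 11.6 to 4.71 ± 1.2 CPM and TRIAE_CS42_2DS_TGACv1_177741_AA0583580 from 6.93 ± 4.69 to 0.933 ± 0.168, with changes of -2.65 ± 0.5 and -2.88 ± 0.55; the last 3 genes had an adjusted p of 0.038. Of the 38 genes, 33 had the same sign in zone A and 37 in zone B, whose libraries are paired by number with those of zone C, and in PC minus CK 19, 16 and 6 had it in zones A, B and C. In zones A and B edgeR called 0 genes, with 4249 and 6012 at an unadjusted p below 0.05. DESeq2 called 48 and 160 there and 691 in zone C, limma-voom 0, 0 and 3. Group quality weights gave 508, 327 and 251 calls (zones A, B, C), and leaving out CK number 3 and PC number 1 gave 30, 86 and 1106. Those libraries belong to neither PD nor CD. They enter this comparison only through the filter, the scaling and the spread estimated over all groups. The median SD was 0.17 to 0.24 in CD and PD groups and 0.27 to 0.46 in CK and PC groups. Few calls here therefore do not show that priming left expression under stress unchanged. With the stricter filter zone C gave 148. Groups did not overlap for 20.2%, 19.9% and 19.6% of tested genes (zones A, B, C). For genes without ties 10% is the average over all splits of the 6 libraries. Genes vary together within a library, so a single split can lie far from that average. Shares of the other splits were not computed, so these shares do not show a difference. The zone C count was 0 without PD number 1 or 3 or CD number 2 or 3, 650 without CD number 1, and 0 without a filter on low counts or with the 12 libraries of the zone. Each of the 4 named genes lost its call without any 1 of the 4 libraries that brought the count to 0 (adjusted p from 0.081 to 0.26), and the 7DS and 2DS genes did so without PD number 2 as well (adjusted p = 0.083 and 0.077). All 4 calls ended without a filter (0.061 each), with the libraries of the zone (0.5) and with the 6 libraries compared (0.18). The 5AL, 2DS and 7DS calls ended with limma-voom (0.095, 0.17 and 0.095) and the random block (0.061, 0.23 and 0.089), and the 2DS call with group quality weights (0.071). Leaving out 1 library in zone B gave at most 1 call, without PD number 1. The F-test for a difference of PD minus CD between zones called 0 genes, with 1600 at an unadjusted p below 0.05; it called 0 by DESeq2, limma-voom and with the block of code and number.

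PC minus CK, which asks what priming left behind after recovery, held 1 called gene in zone B and 1 in zone C, the same gene. TRIAE_CS42_1DL_TGACv1_062373_AA0213460 was at 18.7 ± 8.69 CPM (SD, n = 3) in CK zone C and 0.516 ± 0.142 in PC, a log2 fold change of -5.16 ± 0.75 (SE; edgeR adjusted p = 0.019) and a count ratio of 34.8 (95% interval 24.4 to 51.5). In zone B, where it was named after its values were seen, it had 146, 154 and 21 counts in CK and 1, 0 and 1 in PC, a ratio of 161 (44.3 to 1340). It stood at 3.31 ± 3.13 CPM in CD and 3.98 ± 1.88 in PD in zone C, so it was lower in CD than CK (-2.5 ± 0.64) and higher in PD than PC (2.92 ± 0.71). Both differences reuse the CK and PC libraries by which the gene was chosen, a choice that favours these directions. In CK the gene rose from zone A to C (5.97 ± 0.79). Zone A held 0 calls by edgeR, with 2412 genes at an unadjusted p below 0.05, and by limma-voom, against 48 by DESeq2. In zones B and C DESeq2 called 109 and 165 genes, limma-voom 3 and 70, the random block 2 and 65 and group quality weights 1 and 33. Groups did not overlap for 6.14%, 6.32% and 8.3% of genes, where 10% is the average over splits and a single split can lie far from it. Leaving out PC number 1 gave 371 calls in zone C, and leaving out CK number 3 gave 4 in zones B and C. The zone C count was 0 without CK number 1 or 2 or PC number 2 or 3; the adjusted p of the gene was then 0.097, 0.11, 0.11 and 0.13. Its call also ended with group quality weights (0.36), with the 12 libraries of the zone (0.15) and with the 6 libraries compared (0.39). In zone B the count was 0 without CK number 1 or 2 or PC number 1 or 2, and 2 without PC number 3. Without CK number 3 and PC number 1 in all zones, the counts were 577, 1128 and 3722.

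**Figure D4:**
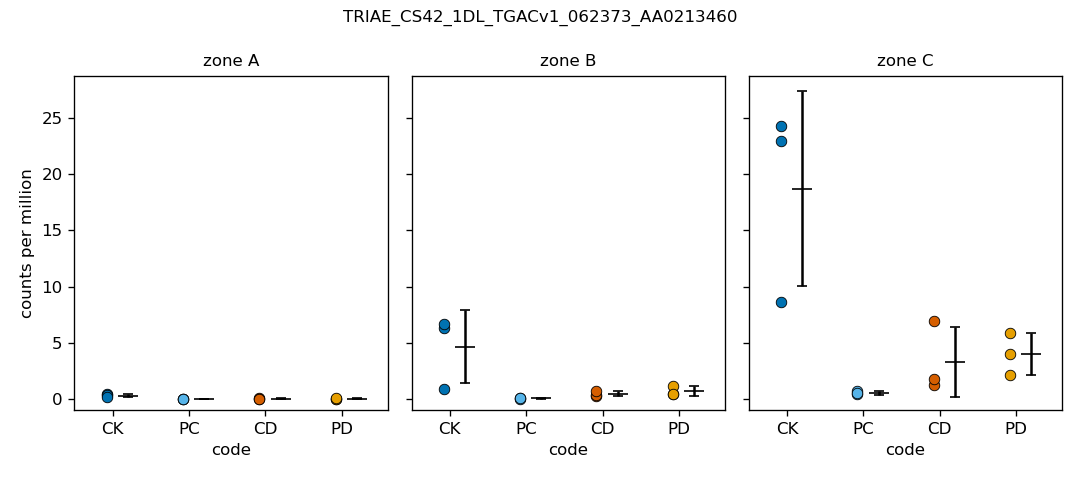
CPM of TRIAE_CS42_1DL_TGACv1_062373_AA0213460 in each library (points) by code and zone, with group means and SD (bars, n = 3). In zone C the CK mean is 18.7 and the PC mean 0.516.

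The difference itself was tested between zones and between primed and unprimed plants, and the counts changed with how the pairing of zones by number was treated. CD minus CK differed between zones for 1 gene, TRIAE_CS42_2AL_TGACv1_093763_AA0286290, chosen after its values were seen, with log2 fold changes of -0.88, 0.6 and 2.57 in zones A, B and C (edgeR adjusted p of the F-test = 0.019); with code and number as a block 226 genes were called. That call ended without CK zone A number 1, without any single CD library of zone A, and without any single CK or CD library of zone C, each of which left 0 calls. PD minus PC differed from CD minus CK for 609 genes in an F-test over the 3 zones. With code and number as a random block it was 30. With counts summed over the zones it was 0, but that is another test, of 1 difference in 12 summed libraries. It dilutes a difference confined to 1 zone. In the F-test over the 3 zones, leaving out CK zone C number 2, PD zone B number 1, PD zone C number 1, CD zone B number 3, CD zone C number 2 or 3, or PC zone C number 1 or 3 gave 358, 388, 368, 381, 339, 321, 1481 and 359 calls.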

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

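All tests of explanations below other than the counts of splits were chosen after the result was seen, as were the tests for PD minus PC between zones and for the codes within each zone. The results on zones and codes are differences between groups found by a test of the difference itself; the positions of libraries and the XLOC loci are patterns noticed in the data.

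CD minus CK differed between zones for 1 gene in the fit without a block, which ignores the pairing of zones by number. With code and number as a block it was 226, with it as a random block 70, and by limma-voom without a block 0. The 10 splits of the CD and CK libraries are too few for a share under 0.05, and the highest of the other splits gave 0. Without CK number 1 of zone A, or any 1 CD library of zone A or CK or CD library of zone C, the count without a block was 0.

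PD minus PC differed between zones for 316 genes, against 8653 with code and number as a block, 7122 with it as a random block, 1994 by DESeq2, 208 by limma-voom, 22 with group quality weights, 47 without a filter, 541 with the stricter filter and 5168 without CK number 3 and PC number 1. The 10 splits are too few for a share under 0.05, with 0 as the highest other. Without PD number 1, 2 or 3 of zone A the count was 75, 104 and 2, and without PC number 1, 2 or 3 of zone A 959, 28 and 37. Zone B gave 154 and 200 without PD number 1 or 2 and 560, 135 and 178 without PC number 1, 2 or 3. Zone C gave 0, 56 and 3 without PD number 1, 2 or 3 and 2087, 8 and 2 without PC number 1, 2 or 3.

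Tested in zone C alone, PD minus PC differed from CD minus CK for 407 genes, 102 higher and 305 lower; 5 of 30 splits, the real one included, gave as many (highest other 4262), so chance is not excluded. DESeq2 gave 1778 (530 higher and 1248 lower), limma-voom 196 (94 and 102), the random block 90 (46 and 44), group quality weights 24, no filter 141 and leaving out CK number 3 and PC number 1 in all zones 5073. Without CK number 2 or 3 the count was 21 and 100, without PD number 1 or 3 it was 29 and 55, without CD number 1, 2 or 3 it was 1258, 42 and 19, and without PC number 1 or 3 it was 2684 and 9. In zones A and B edgeR called 0 genes, with 3546 and 5465 at an unadjusted p below 0.05, DESeq2 43 and 153, and limma-voom 1 and 0. Leaving out PC number 1 gave 12 in zone A and 5 in zone B, where leaving out CK number 3 or PD number 3 gave 2 and 1. The highest of the other splits gave 326 and 1595 there; a real count of 0 leaves a count of splits nothing to test.

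Over the 3 zones PD minus PC differed from CD minus CK for 609 genes, and 8 of 30 splits, the real one included, gave as many, the highest 9898, so chance is not excluded; a split with several times the real count points to a structure of the samples. Without CK number 2, PD number 1, CD number 2 or 3 or PC number 1 or 3 of zone C, or PD number 1 or CD number 3 of zone B, the count was 358, 368, 339, 321, 1481, 359, 388 and 381. The test takes the zones of a code and number as independent, although their libraries deviated together. With code and number as a random block limma-voom called 30 genes, against 566 by the same fit without it, so counting zones as independent is a candidate explanation for most calls. An effect of priming on the stress response stays open as untested by this.

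CK number 3 and PC number 1 lay towards CD and PD in all 3 zones, at 0.34 to 0.49 and 0.27 to 0.43. An exchange with a CD or PD library is argued against by their highest position of 0.49, with no CD or PD library below 0.77. An exchange between CK and PC would stay at the unstressed end of this scale, so these positions cannot show it. For PC minus CK in zone C, grouping PC number 1 with CK number 2 and 3 gave 4314 calls, against 1 with the real labels. The same grouping gave 0 calls in zones A and B. In zone C these 3 libraries had the highest positions among CK and PC (0.43, -0.02 and 0.34). Exchanging PC number 1 with CK number 3 gave 75, 0 and 749 calls (zones A, B, C). Whether such an exchange took place was not tested. Library depth is argued against by mean positions of 0.45 and 0.37 after all libraries were thinned to 14.2 M counts, and a shift of zone boundaries by 0.47 and 0.44 on genes flat over the zones of the other code. Why they lie towards CD and PD stays open: a mixture with stressed tissue and a difference between plants were not tested.

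XLOC loci had a median log2 fold change of 0.11 in CD minus CK in zone C, against -0.08 for the other genes. Random sets of other genes matched on mean expression reached at most -0.1 and sets matched on length at most -0.06, which argues against expression level and length as the source. By library the difference did not reach a smaller p than 0.2 in CD minus CK (two-sided exact permutation p = 0.4, 0.2 and 0.2 in zones A, B and C, n = 3, smallest possible 0.1). In PD minus PC it was 0.6, 0.1 and 0.1, with every PD library above every PC library in zones B and C. No biological explanation was tested.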

How the results depend on the processing

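The fits without 6 libraries, to the 6 libraries compared, with group weights, with a random block and on summed counts were chosen after the data were seen. A log2 fold change of at least 1 and median-ratio factors left all 18 counts within 1.5 times. Of the values of named genes under alternatives, 399 of 504 kept their call, 105 lost it and 0 reversed. The cause of the changes below was not tested. DESeq2 gave 5084 and 8659 calls for CD minus CK (zones A, B), 48, 160 and 691 for PD minus CD, 48, 109 and 165 for PC minus CK, 15 for zone differences in CD minus CK and 2476 for the difference of PD minus PC from CD minus CK. Group weights gave 10536 and 11421 for CD minus CK (A, B), 13207 for PD minus PC (C), 508, 327 and 251 for PD minus CD, 33 for PC minus CK (C) and 4 for zone differences in CD minus CK. Limma-voom gave 3 for PD minus CD (C), 3 and 70 for PC minus CK (B, C) and 0 for zone differences. No filter gave 0 for PD minus CD (C) and 5 for PC minus CK (B); the stricter filter gave 148 and 2, and correlations of both responses of 0.68, 0.69 and 0.66. Only the 6 libraries gave 3290 for CD minus CK (A), 2127, 0 and 0 for PD minus PC, 1 and 0 for PD minus CD (A, C), 0 and 0 for PC minus CK (B, C) and 6924 from zone B to C. Only the libraries of the zone gave 1510 and 2134 for CD minus CK (B, C), 14275 for PD minus PC (C), 0 for PD minus CD (C) and 0 and 0 for PC minus CK (B, C). The random block (correlation 0.51) gave 3198 for CD minus CK (A), 1 and 8 for PD minus CD (B, C), 2 and 65 for PC minus CK (B, C), 29709 and 25866 for zones A to B and B to C, 70 for zone differences in CD minus CK and 30 for the difference of responses. Summed counts gave 0 for the difference of responses, in a test of 1 difference over the zones together. The replicate block of code and number gave 30883, 27281 and 226 for these zone results. The replicate block of number over all groups gave 66 for PD minus CD (C) and 9 and 27 for PC minus CK (B, C). Without CK number 3 and PC number 1 the counts were 14562, 18549 and 17739 for CD minus CK, 21649, 27009 and 33504 for PD minus PC, 30, 86 and 1106 for PD minus CD, 577, 1128 and 3722 for PC minus CK, 4 for zone differences and 5851 for the difference of responses.

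Without each library in turn, CD minus CK ranged from 203 to 4615, 402 to 8570 and 1535 to 8734 (zones A, B, C) and PD minus PC from 1526 to 13277, 2461 to 19785 and 10730 to 28539. PD minus CD ranged from 0 to 0, 0 to 1 and 0 to 650, and PC minus CK from 0 to 0, 0 to 4 and 0 to 371. Zone results ranged from 9051 to 16145 (A to B), 30267 to 33474 (A to C) and 5571 to 11291 (B to C). Zone differences ranged from 0 to 1 (CD minus CK), 0 to 0 (PD minus CD) and 0 to 2087 (PD minus PC). The difference of responses ranged from 321 to 1481 over all zones and from 0 to 12, 0 to 5 and 9 to 2684 by zone, and correlations from 0.47 to 0.59, 0.47 to 0.57 and 0.48 to 0.57. The gene list tests were not run, since no ID had a name. No pseudocount enters the p-values of edgeR and DESeq2. The limma-voom fits, also those with group weights or a random block, add a small count before taking logs. The log2 fold changes of edgeR carry a small count too, which matters most for genes with 0 counts in a group. The prior count of 2 in log2 CPM was not varied. It enters the principal components, spreads, correlations of libraries, positions, slopes and values of gene groups by library. Depth limits what 0 counts allow. In simulated data with few changed genes no 2-fold change was called, whereas in the comparisons with many calls some lay below 2-fold, as in CD minus CK in zone C (5216 of 6720 at 2-fold or more).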

Other observations

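The comparisons of neighbouring genes and of subgenomes were chosen after the data were seen, and the counts of splits were planned. Shares of calls in the A, B and D subgenomes are given without a test of a difference between them. In CD minus CK in zone C, 3.3%, 3.25% and 3.72% of the genes of A, B and D were higher and 6.52%, 6.71% and 6.81% lower; in PD minus PC they were 11.9%, 11.4% and 12.5% higher and 19.3%, 20% and 19.6% lower. Genes next to each other in the order of their IDs changed alike: the log2 fold changes of 21539 neighbouring pairs correlated at 0.14 in CD minus CK and 0.13 in PD minus PC in zone C and at 0.15 between zones C and A of CK. The highest of 100 draws of random pairs gave 0.01, 0.02 and 0.03. These correlations are across genes, which are not independent replicates.

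The 6 libraries of a comparison make 10 splits into 3 and 3, the real one included, too few for a share under 0.05. In CD minus CK the real counts of 1989, 4973 and 6720 (zones A, B, C) stood beside a highest other count of 0, 1 and 0. In PD minus PC the real counts of 8071, 11997 and 21540 stood beside 0, 0 and 7090, the last from PD number 1 and 3 with PC number 1. In PD minus CD they were 0, 0 and 38 beside 0, 0 and 1, with 1 split, the real one, giving 38; where the real count is 0 all 10 splits give as many by construction. In PC minus CK they were 0, 1 and 1 beside 75, 0 and 4314, with 1 and 4 splits giving as many in zones B and C, the real one included. The 4314 came from PC number 1 with CK number 2 and 3 and points to a structure of the samples in zone C. That grouping gave 0 in zones A and B. The zones of CK gave 16349 (A to B), 34567 (A to C) and 11121 (B to C) beside 0, 0 and 145; the 3 other splits that part all 3 numbered pairs gave at most 0. The difference of PD minus CD between zones gave 0 in all 10 splits.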
